A study of Mus musculus with 6 samples.

How the data were processed

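Gene expression was measured on 6 Affymetrix Mouse 430A2.0 arrays, 1 per mouse, in bone marrow cells sorted as lineage-negative, Sca-1-positive and c-Kit-positive (LSK), the fraction that holds haematopoietic stem cells and multipotent progenitors. Per the series' design text, 3 mice carried a floxed and a null Ott1 allele with the Mx1-Cre transgene, and 3 littermate controls kept a wild-type Ott1 allele. All received 250 mcg of pIpC, the inducer of Cre, in each of 3 doses from 6 weeks of age, and marrow was taken 6 weeks later. About 10000 cells per mouse were sorted after bead depletion of lineage-positive cells, and 50 ng of total RNA was amplified and labelled.

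Per the submitters' processing notes and the design text, the authors preprocessed the raw values with robust multi-array analysis (RMA) in Bioconductor. RMA corrects background, sets the probe distributions of all arrays equal and summarises each probe set. Versions, any later scaling and the library of probe definitions are not given in the sources used here. The deposited values were on a linear intensity scale, with medians between 183 and 199 per array and no missing value. The test planned for log2 values was therefore run on the log2 of these intensity values, with no pseudocount. No detection calls were used here, so dim genes could not be told from absent ones, and the number of arrays limits the precision. No array repeated another over all probe sets (0 pairs).

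The array tables held 22690 probe sets, of which 20393 were paired with 1 gene symbol by the platform annotation, 691 with several symbols and 1606 with none in the table given. Of the 64 control probe sets, 13 carried the symbol of a mouse gene and stayed in the gene table, where 1 of them stood for Gapdh. Of the gene identifiers behind the single symbols, 99.9% were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table was otherwise used only for gene order, and no coordinates are given because no genome build is named for the arrays. For each of 12394 genes the probe set with the highest mean over all 6 arrays stood for the gene. This choice mattered for 4958 genes with several probe sets. Ly6a and Ddx3y, which the rule for naming genes includes, were not analysed here because no probe set with a single symbol carried them.

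Knockout minus control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, group as the only term). Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 4 residual and 2.90 prior degrees of freedom. Errors of log2 changes are limma's moderated standard errors, and those of group means are standard deviations over 3 mice. For the targeted gene an exact permutation test over all ways of dividing the arrays was added.

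Gene lists (32, written from general knowledge) covered ageing and quiescence of stem cells, lineages, other cell types a sort could hold, the cell cycle, stress and metabolism. The 31 lists with at least 5 measured genes were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with a correlation estimated per list, and fry, which asks whether a list's own genes move one way on balance, were alternatives. The lists overlap: 60 genes stood in more than 1 list. Within a list, calls were also counted with p-values adjusted over the list alone.

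The genes named in the text were chosen by a rule. It took the targeted gene, then the 12 largest rises and the 12 largest falls past the threshold among genes above the 40th percentile of mean log2 intensity (7.04) whose knockout and control values did not overlap. It also took, in each list described, up to 4 members past the threshold by smallest p, or the 2 with the smallest p where none passed, and a few fixed sort, sex-linked and interferon genes. Groups, lists, tests, this rule and the alternatives were fixed before the data were examined. Genes named outside the rule are said to have been chosen after their values were seen.

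The alternatives were the replicate number as a block, leaving out each array in turn, quantile normalization of the deposited values, centring each array on its median, array weights, eBayes with trend and robust options, leaving out genes up to the 40th percentile, averaging probe sets, leaving out probe sets with the suffixes x or s, testing every probe set, a looser threshold of 0.1, a plain t-test, and for the lists an estimated correlation, fry and genes of 1 list only. Sex was not used as a covariate, since no array stood apart in the Y-linked Eif2s3y and Kdm5d, whose values on the 6 arrays spanned 0.57 and 0.45 log2 units. The dimmer Uty and Xist spanned 0.91 and 1.27.

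The fits were tested on simulated data with each gene's mean and spread taken from these arrays. The noise was drawn independently for each gene and was equal in both groups. Real lists had estimated correlations of up to 0.35, so the false calls below do not measure the error in the real data. Among 12394 simulated genes, 200 were changed, 100 by 1 log2 unit and 100 by 2, and a list of 30 further genes was raised by 0.7. The fit made 178 calls, which held 66.0% of the smaller and 93.0% of the larger changes, 9 of the list genes and 10 false calls. Of the calls among the 200 genes 0 had the wrong direction. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.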

Results

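The data set held 6 arrays of sorted LSK marrow cells, 3 from mice in which Ott1 (Rbm15) had been deleted in adult blood-forming cells and 3 from littermate controls. Rbm15 encodes a nuclear RNA-binding protein of the SPEN family that is a partner of the writer complex for N6-methyladenosine. Median intensities lay between 183 and 199 on all 6 arrays. Over all genes the correlation between arrays was 0.990 to 0.991 among knockout mice, 0.994 among controls and 0.986 to 0.991 between the groups. The leading principal component, with 40.2% of the variance, placed the 3 knockout arrays at 17.8 to 20.4 and the 3 control arrays at −23.5 to −16.2. The comparison addressed whether stem cells without Ott1 carry expression features of aged stem cells and how genes of quiescence stand in them.

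The targeted gene Rbm15, read by 1 probe set (1434514_at), fell by 4.09 ± 0.59 on the log2 scale (SE, n = 3 per group; adjusted p = 0.0450, limma). Log2 intensities were 5.81, 6.47 and 3.98 in the knockout mice and 9.80, 9.57 and 9.15 in the controls. Relative to the control mean, 7.69%, 12.2% and 2.16% of the signal remained in knockout replicates 1, 2 and 3. All 3 knockout values lay under the 40th percentile of genes (7.04), so the remaining signal may be background and the size of the fall is uncertain. The exact permutation test gave p = 0.1, the smallest value that 3 against 3 mice allow. Where the probe set lies relative to the deleted part of the gene is not given in the sources used here. Leaving out any 1 array kept the fall, between −4.62 and −3.37, with an adjusted p of 0.0522 to 0.142, and tested over every probe set the adjusted p was 0.0603. The list of Rbm15 with its partners, paralogs and other genes of N6-methyladenosine and mRNA export had 1 of 13 members past the threshold, Rbm15 itself; adjusted over the list alone 1 fell and 1 rose. The latter was the paralog Spen, chosen after its values were seen, at 0.58 ± 0.12 (adjusted p = 0.0971).

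The largest changes between the groups included higher platelet genes and lower MHC class II genes in the knockout. Selp, which encodes the adhesion molecule P-selectin of platelets and endothelium, rose 5.21-fold (log2 change 2.38 ± 0.31, adjusted p = 0.0359). Gp1bb and Gp5, subunits of the platelet receptor for von Willebrand factor, rose by 2.11 ± 0.17 (adjusted p = 0.0201) and 1.61 ± 0.24 (adjusted p = 0.0457). Cd74, the invariant chain that escorts MHC class II molecules, fell by 1.55 ± 0.21 (adjusted p = 0.0378), and the class II chains H2-Aa and H2-Eb1 fell by 1.58 ± 0.24 and 1.68 ± 0.22 (adjusted p = 0.0457 and 0.0359; all log2 changes with SE, n = 3 per group).

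Other genes with large rises were Spats2 (2.99), Calml4, a calmodulin-like gene (2.39), Ctse, which encodes the protease cathepsin E (2.15), St3gal1, a sialyltransferase (2.12), Gem, a small GTPase (1.93), Aif1l (1.81), Sult1a1, a sulfotransferase (1.73), Apoe, a lipid carrier (1.65), and Pim2, a kinase that promotes survival (1.49). Their standard errors were 0.16 to 0.31 and their adjusted p-values 0.0201 to 0.0457. The further large falls were Cnn3, which encodes the actin-binding calponin 3 (−2.19), Dzip1 (−1.79), Scd1, a fatty acid desaturase (−1.66), Prss16, a serine protease (−1.63), Fbp1, a gluconeogenic enzyme (−1.58), Mpeg1, a pore-forming protein of macrophages (−1.50), Eno2, an enolase (−1.28), and Prr15 (−1.25). Their adjusted p-values were 0.0201 to 0.0450. The control means of Spats2, Calml4, Aif1l and Sult1a1 and the knockout means of Scd1, Prss16 and Eno2 lay under the 40th percentile of genes (7.04), so the sizes of these changes are uncertain. A dimmer probe set of Ctse (−0.25) and of Scd1 (0.14) went against the brighter ones, neither past the threshold. With averaged probe sets Ctse (0.95), Dzip1 (−0.73), Scd1 (−0.76) and Prr15 (−0.68) no longer passed (adjusted p = 0.0870, 0.0758, 0.137 and 0.0676).

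Of 12394 genes, 103 (0.83%) passed adjusted p 0.05, 64 higher and 39 lower in the knockout. In all 103 the 3 knockout values lay apart from the 3 control values, as they did in 20.9% of all genes, where chance gives 10%. At unadjusted p under 0.05 there were 1853 genes, against 620 expected by chance. The split of the calls depended on scaling, with 39 higher and 37 lower after a further quantile normalization and 34 higher and 42 lower with arrays centred on their medians. The smallest adjusted p was 0.0201, and leaving out 1 array left 0, 18 and 0 calls without knockout replicates 1, 2 and 3 and 10, 3 and 3 without control replicates 1, 2 and 3.

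**Figure D1:**
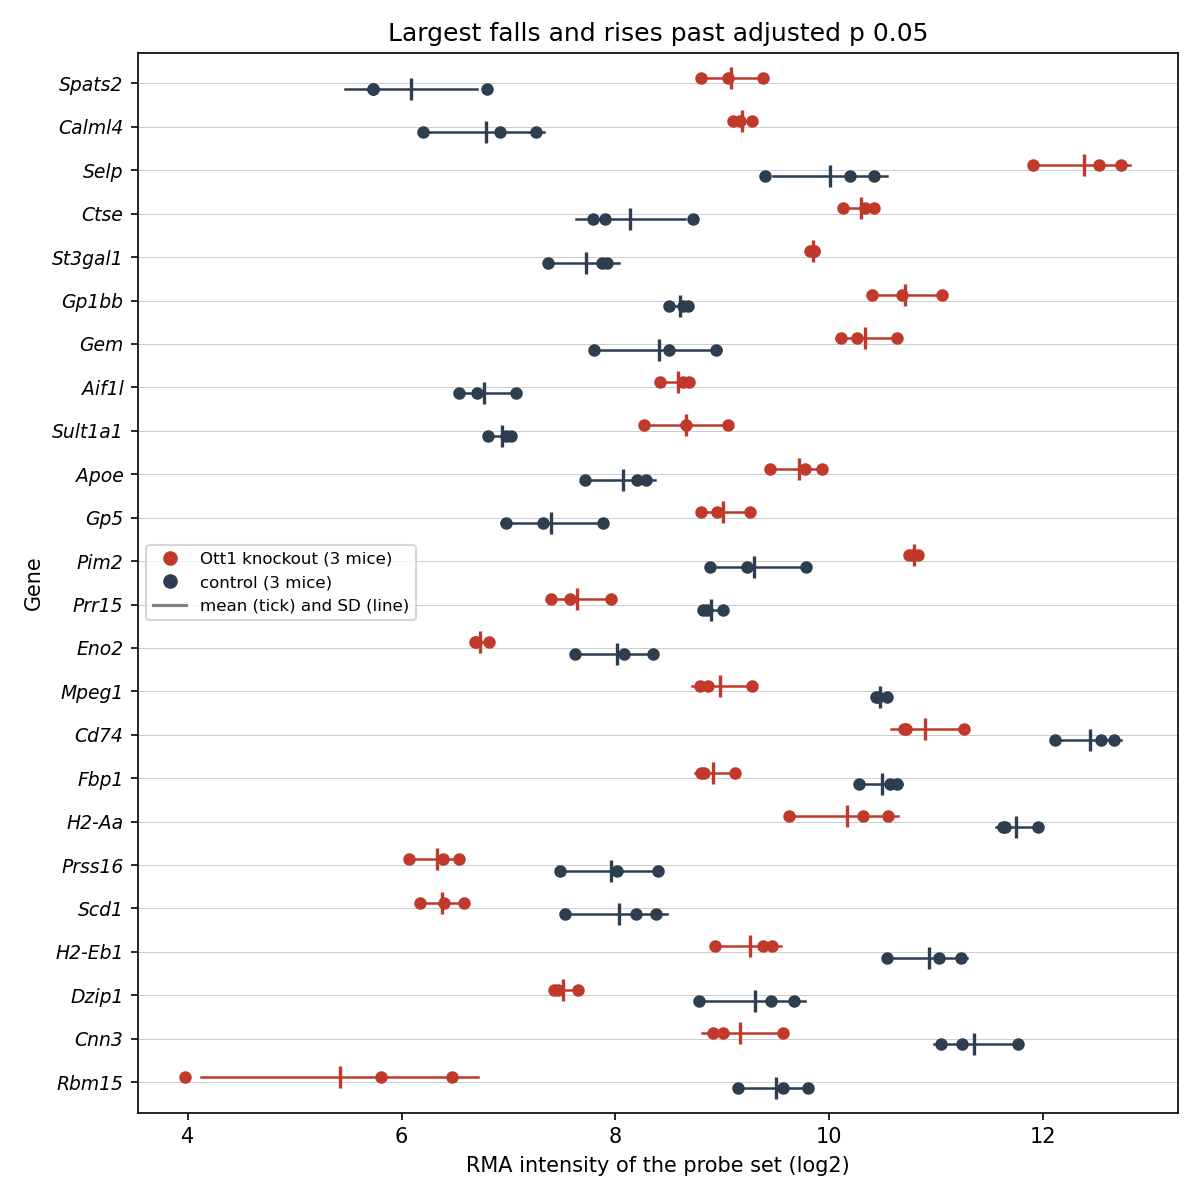
Log2 RMA intensity (horizontal axis) of the genes with the largest rises and falls past adjusted p 0.05 (vertical axis) in 3 Ott1 knockout mice (red) and 3 controls (dark), each point 1 mouse, ticks the group means and lines the SD. Knockout and control points lie apart for each gene shown, and Rbm15 spans 3.98 to 6.47 in the knockout mice against 9.15 to 9.80 in the controls.

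Genes known to be higher in aged than in young mouse stem cells stood higher in the Ott1 knockout. Neo1, which encodes the netrin receptor neogenin, rose by 3.23 ± 0.29 on the log2 scale (adjusted p = 0.0201), from a mean of 5.22 ± 0.46 to 8.45 ± 0.45 (SD, n = 3). The control mean lay under the 40th percentile of genes (7.04), so the size of this rise is uncertain. Selp and Sult1a1 rose by 2.38 and 1.73, as given above. Of the 34 measured members 3 rose, 0 fell and 31 did not pass; adjusted over the list alone 17 rose and 0 fell. The list's median change was 0.67, its mean change 0.85, and 27 members were higher and 7 lower. The mean shift was 0.83, 0.61 and 1.11 in knockout replicates 1, 2 and 3, against −0.072 to 0.039 in the controls. Camera placed the list above other genes at the preset correlation (adjusted p = 7.93e-08), and this call was lost with an estimated correlation (adjusted p = 0.382), while fry put its own direction at an adjusted p of 0.0407.

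Megakaryocyte and platelet genes moved with the ageing list, with which they share 5 members. Besides Gp1bb, Gp5 and Selp, the members that rose were Zfpm1, which encodes the GATA cofactor FOG1 (1.08 ± 0.16, adjusted p = 0.0455), and Rab27b, a GTPase of granule release (1.04 ± 0.14, adjusted p = 0.0405). Of 25 measured members 5 rose, 0 fell and 20 did not pass; adjusted over the list alone 10 rose. The mean change was 0.65 (camera adjusted p = 7.22e-07; adjusted p = 0.382 with an estimated correlation). Among the 23 measured endothelial and stromal genes 0 passed, and 2 passed adjusted over the list alone. The list's mean change was 0.30 (camera adjusted p = 0.0455; adjusted p = 0.382 with an estimated correlation). Its leading members were Bgn, which encodes the matrix proteoglycan biglycan (1.13 ± 0.19, adjusted p = 0.0594), and Tie1, an endothelial receptor kinase (0.99 ± 0.23, adjusted p = 0.115). The endothelial list no longer passed without knockout replicate 2 or 3 or control replicate 1 (adjusted p = 0.0695, 0.0756 and 0.0965), after a further quantile normalization (0.0550) or without shared members (0.0877), and Bgn passed with averaged probe sets (0.0387), without dim genes (0.0450) and with trend and robust options (0.0413). Without dim genes the endothelial mean was 0.48.

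Among genes of long-term and quiescent stem cells, Tek, which encodes the angiopoietin receptor TIE2, rose 2.74-fold (log2 change 1.45 ± 0.22, adjusted p = 0.0450). Of 45 measured members 1 rose and 44 did not pass; adjusted over the list alone 4 rose and 1 fell. The list had a mean change of 0.22 and a median of 0.23 and did not pass camera (adjusted p = 0.0941; adjusted p = 0.737 with an estimated correlation). It did pass without knockout replicate 2 or control replicate 2 (adjusted p = 0.0315 and 0.0230), under both other scalings (0.0371 and 0.0189) and without x and s probe sets (0.0399). The list also holds genes of multipotent progenitors, among them a gene that stands in the lymphoid list, so it does not read long-term stem cells alone.

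The means of both cell cycle lists differed by less than the spread between mice. Of 41 S-phase genes 0 passed, with a mean change of −0.016 (camera adjusted p = 0.382), and of 55 G2/M genes 0 passed, with a mean of −0.019 (camera adjusted p = 0.350); adjusted over the list alone 0 passed in both. The members with the smallest p were Tk1, a thymidine kinase (0.45 ± 0.10, adjusted p = 0.114), and Gins4, a replication factor (0.40 ± 0.10, adjusted p = 0.146), in S phase. In G2/M they were Cenpe, a kinetochore motor (0.46 ± 0.10, adjusted p = 0.106), and Mki67, the proliferation marker Ki-67 (0.38 ± 0.11, adjusted p = 0.184). In these 4 genes the knockout values lay above the control values, without passing the threshold. The mean shift of the G2/M list was −0.10 and −0.083 in knockout replicates 1 and 2 and 0.13 in replicate 3. Without replicate 3 the list passed as lower (mean −0.093, camera adjusted p = 0.00836), and without replicate 1 its direction turned (mean 0.023, adjusted p = 0.806). The S-phase mean also changed sign, between −0.092 with centred arrays and 0.034 with averaged probe sets.

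Genes of mature B and plasma cells were lower in the knockout, led by the class II genes given above. Spib, an Ets factor of B cells and plasmacytoid dendritic cells, fell by 0.95 ± 0.15 (adjusted p = 0.0499) at an intensity near the low end (5.53 to 4.58). Of 19 measured members 0 rose, 4 fell and 15 did not pass; adjusted over the list alone 7 fell. The mean change was −0.91 (camera adjusted p = 1.12e-09; adjusted p = 0.340 with an estimated correlation; fry adjusted p = 0.0407). The members that fell were 3 class II genes and Spib, which dendritic cells also express. Of the 15 members outside class II 14 were lower. They ran from −2.84 ± 0.87 in Jchain, the joining chain of antibodies (adjusted p = 0.213), to 0.16 ± 0.13 in Cr2, a complement receptor (adjusted p = 0.595), both chosen after their values were seen. The B cell genes Cd79a and Cd79b, chosen likewise, stood at −0.11 and −0.19 (limma adjusted p = 0.777 and 0.569).

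Lymphoid genes of early progenitors were lower on average, with a large spread among the knockout mice. Ccr7, a chemokine receptor of lymphocytes, fell by 1.04 ± 0.15 (adjusted p = 0.0436), and Cnr2, the cannabinoid receptor of immune cells, rose by 1.15 ± 0.15 (adjusted p = 0.0378). Both were dim, with control means of 5.80 and 5.91. Of 33 measured members 1 rose, 1 fell and 31 did not pass; adjusted over the list alone 1 rose and 4 fell. The mean change was −0.47 and the median −0.13 (camera adjusted p = 0.00220; adjusted p = 0.737 with an estimated correlation). The mean shift was −0.26, −0.25 and −0.88 in knockout replicates 1, 2 and 3. In knockout replicate 3 the recombination-site polymerase gene Dntt, chosen after its values were seen, read 8.92 against 12.05 and 11.80 in replicates 1 and 2 and 12.92 to 13.08 in the controls (log2 change −2.08 ± 0.77, adjusted p = 0.281). Without replicate 3 the list's mean was −0.26 (camera adjusted p = 0.0170). The B cell list was also lowest in replicate 3, with shifts of −0.74, −0.79 and −1.21.

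Of 35 genes of committed granulocyte and monocyte progenitors 0 passed, also adjusted over the list alone, with a mean change of −0.26 (camera adjusted p = 0.00203; adjusted p = 0.737 with an estimated correlation). The members with the smallest p pointed opposite ways, the cytokine receptor gene Csf2rb2 at 0.70 ± 0.18 (adjusted p = 0.150) and the granule gene Nkg7 at −0.74 ± 0.22 (adjusted p = 0.200). The shift was −0.56, 0.023 and −0.23 in knockout replicates 1, 2 and 3 and 0.26, −0.24 and −0.019 in control replicates 1, 2 and 3. The list no longer passed without knockout replicate 1 (mean −0.10, adjusted p = 0.145) or control replicate 1 (mean −0.13, adjusted p = 0.174), and its mean was −0.40 without knockout replicate 2.

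Of 55 interferon response genes 1 fell, Gbp3, an interferon-induced GTPase (−0.98 ± 0.14, adjusted p = 0.0447), and 54 did not pass; adjusted over the list alone 3 fell. The list's mean change was −0.17 (camera adjusted p = 0.00388; adjusted p = 0.737 with an estimated correlation), and it no longer passed without knockout replicate 3 (adjusted p = 0.0759). Mx1, whose promoter drives Cre in these mice, stood at −1.09 ± 0.42 (adjusted p = 0.292). Knockout replicate 3 read 6.06 for Mx1, against 7.50 and 7.79 in replicates 1 and 2, and without it the change was −0.56.

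Among 39 genes of glycolysis and hypoxia 2 fell and 37 did not pass; adjusted over the list alone 3 fell. The 2 were Eno2, which encodes a glycolytic enolase, and Fbp1, which encodes a bisphosphatase of glucose synthesis. The list's mean change was −0.15 and its median −0.026 (camera adjusted p = 0.00751; adjusted p = 0.340 with an estimated correlation), and it no longer passed with averaged probe sets (mean −0.097, adjusted p = 0.0591). Of 95 genes of mitochondrial ribosomes and protein import 1 rose, Mrpl43, a protein of the large mitochondrial ribosomal subunit (0.74 ± 0.10, adjusted p = 0.0388), and the count was the same adjusted over the list alone; 76 members were higher and 19 lower. Their mean change was 0.13 (camera adjusted p = 0.00386; adjusted p = 0.737 with an estimated correlation), and without control replicate 2 the list no longer passed (adjusted p = 0.140). With centred arrays the mean was 0.057 and 55 of the 95 were higher.

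Markers of other cell types were read beside these groups. Of 15 mast cell and basophil genes 1 rose, Cma1, the mast cell chymase (1.33 ± 0.17, adjusted p = 0.0357; dim in the controls, at a mean of 6.03), with 4 higher and 1 lower adjusted over the list alone, a mean change of 0.28 and a camera adjusted p of 0.147. Among 24 macrophage and dendritic cell genes Apoe rose and Mpeg1 fell, with 2 higher and 2 lower adjusted over the list alone. That list's mean change was 0.014 and turned negative under both other scalings (−0.029 and −0.063), and its test pointed lower (camera adjusted p = 0.942). Of 22 mature neutrophil genes 0 passed, also adjusted over the list alone (mean −0.16, camera adjusted p = 0.104), and the shift was −0.49 in knockout replicate 1 against −0.012 and 0.010 in replicates 2 and 3, beside the low granulocyte and monocyte shift of replicate 1. The neutrophil members with the smallest p were Clec4d, a lectin receptor (0.44 ± 0.10, adjusted p = 0.126), and Chil3, a chitinase-like protein (−0.70 ± 0.19, adjusted p = 0.161). Of 19 T and NK cell genes 0 passed, also adjusted over the list alone (mean −0.068, median 0.0037, camera adjusted p = 0.518), with the T cell surface genes Cd5 at −0.65 ± 0.16 (adjusted p = 0.145) and Cd6 at −0.27 ± 0.12 (adjusted p = 0.360; −0.17 without control replicate 3). The sort gene Kit stood at −0.12 ± 0.14 (adjusted p = 0.713), and its dimmer probe set pointed the other way (0.33). With 1 array left out the Kit change lay between −0.21 and −0.026.

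In total 9 of 31 lists passed camera at the preset correlation, 4 higher and 5 lower, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. For the endothelial and glycolysis lists the estimates (−0.020 and −0.012) lay below the preset 0.01, so a higher correlation did not cost them their calls. The estimates rest on 4 residual degrees of freedom and are themselves imprecise. Fry called 6 lists by their own direction, 5 of the 9 and the mast cell list, but not the lymphoid, granulocyte and monocyte, interferon and mitochondrial lists (adjusted p = 0.472, 0.596, 0.472 and 0.283). Each of the 9 kept its direction under both other scalings. When the 6 arrays were divided into 3 and 3 in all 10 possible ways, 5 of them, the genotype split included, gave 9 called lists. The genotype split gave the smallest p for 5 of the 9 lists, namely the ageing, megakaryocyte, endothelial, B cell and glycolysis lists. Of these, the ageing and B cell lists also passed in 5 other splits each and the megakaryocyte list in 3. The endothelial and glycolysis lists passed in 0 others. Each other split still held unequal numbers of knockout mice on its sides, so part of any genotype shift remains in it. A list with a large shift can therefore pass there, and these counts do not rank the lists by their link to genotype. In other splits the absolute means of the ageing, B cell and megakaryocyte lists reached 0.47, 0.49 and 0.38, against 0.85, 0.91 and 0.65.

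**Figure D2:**
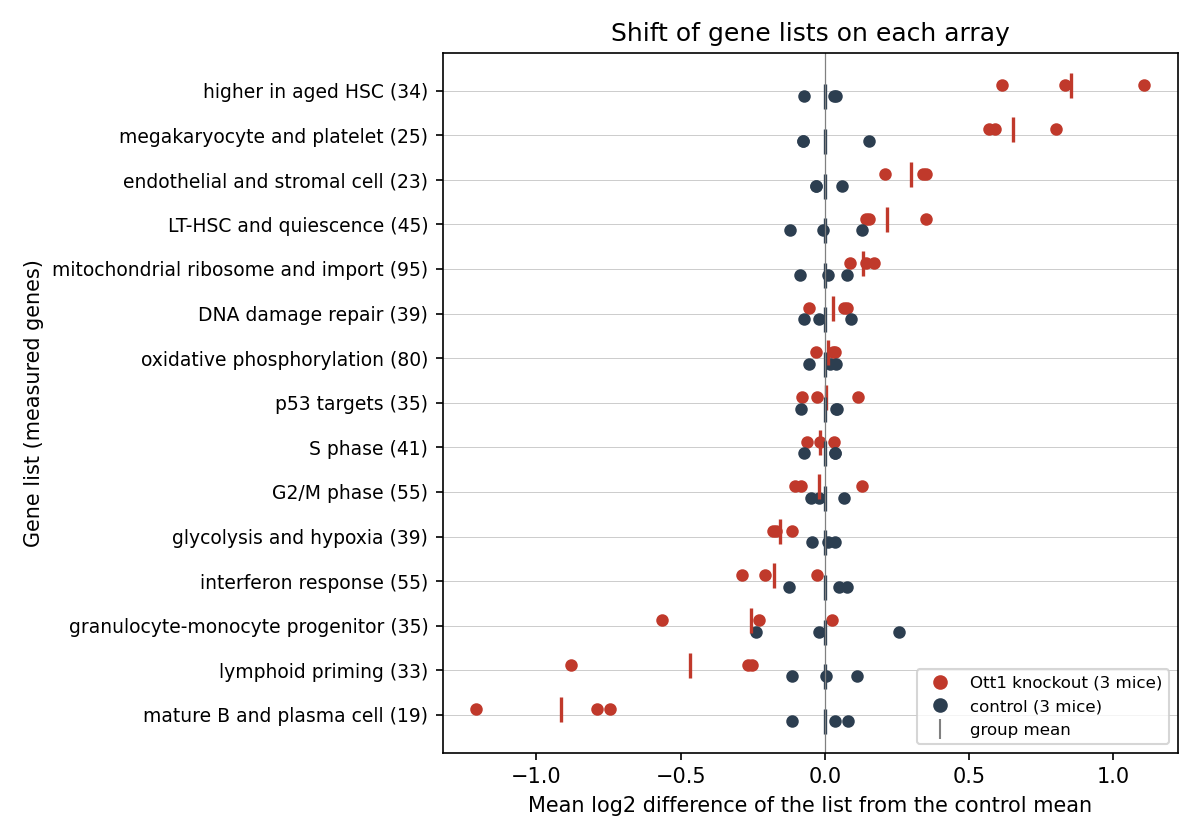
Mean log2 difference of each gene list from its control mean (horizontal axis) on each array, with the number of measured genes after the list's name (vertical axis); points are mice, 3 Ott1 knockout (red) and 3 control (dark), and ticks are group means. The ageing list lies at 0.61 to 1.11 in the knockout mice and the B cell list at −1.21 to −0.74, while the S-phase points of both groups overlap; with centred arrays the oxidative phosphorylation, DNA repair and p53 means change sign.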

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

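The tests of other cell types, of undeleted cells and of array quality described here were chosen only after the results were seen. Centring each array on its median, quantile normalization and the count of other splits were fixed before the data were examined. Only the use of these scalings to weigh the rise of the ageing list was chosen afterwards. Of the 2246 probe sets with no gene or several genes in the annotation, which the comparison by gene did not use, 10 passed adjusted p 0.05 between knockout and control (limma), 6 higher and 4 lower, and 286 had an unadjusted p under 0.05. Of the 64 control probe sets 0 passed.

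The ageing list had the largest mean rise of the lists (0.85), a call lost with an estimated correlation (adjusted p = 0.382). A constant offset between arrays is argued against, since the list's mean change was 0.78 with each array centred on its median. Centring shifts each array by a constant and cannot address scaling that depends on intensity. After a further quantile normalization, which sets the distributions of the arrays equal, the mean was 0.81. Platelets or megakaryocytes carried into the sort, which the c-Kit and Sca-1 gate should remove unless stuck to sorted cells, may contribute: the 16 expressed megakaryocyte genes outside the ageing list had a median change of 0.40 with quartiles of 0.15 and 1.09, 12 were higher, and the abundant platelet gene Pf4, chosen after its values were seen, stood at 0.31 ± 0.20. A larger share of long-term stem cells within the LSK gate stays open too. The 44 genes of the long-term and quiescent list outside the ageing list had a median change of 0.19. Camera gave p = 0.375 with an estimated correlation and 0.0454 with the preset one. As that list also holds genes of multipotent progenitors, the test reads long-term stem cells only in part. A change within stem cells that lack Ott1, which the genotype names, was not tested apart from these explanations.

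The class II genes Cd74, H2-Aa, H2-Eb1 and H2-Ab1 (the last chosen after its values were seen) had a median change of −1.56 in the knockout. Fewer mature B or plasma cells carried past the depletion of B220 and CD19 may contribute. The 15 other members of that list had a median change of −0.42 with quartiles of −1.11 and −0.28. Of these, 11 lay under the 40th percentile in the controls. The B cell genes Ms4a1 and Cd79a, dim in the controls (4.18 and 5.76), stood at −0.21 and −0.11. The brighter antibody genes Ighm and Jchain (13.45 and 10.47) stood at −1.26 and −2.84, without passing the threshold. All were chosen after their values were seen, and they do not decide the question. Fewer dendritic cells or macrophages, which the gate should remove, could account for the fall of Cd74, H2-Aa, H2-Eb1, Mpeg1 and Spib together, but 11 expressed genes of those cells went both ways, with a median of −0.017 and quartiles of −0.45 and 0.31, which decides nothing. Lower class II expression within progenitors that lack Ott1 remains open and untested.

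Lymphoid genes were lowest in knockout replicate 3, which also had the least Rbm15 signal. Undeleted cells of ordinary composition in replicates 1 and 2 could contribute: over all 33 lymphoid genes these lay 0.62 and 0.63 above replicate 3 on average. With replicate 3 taken as fully deleted, 1 Rbm15 probe set gave undeleted shares of 5.65% and 10.3%, which would give 0.14 and 0.22. The Rbm15 values of all 3 knockout mice lay under the 40th percentile of genes (7.04), so these shares may hold background. The excess of 0.48 and 0.41 compares single mice, and the spread between controls (SD of the list mean 0.11) leaves 95% t intervals of −0.21 to 1.17 and −0.28 to 1.10, so the test decides nothing. As to a poor array, replicate 3 lay no farther from the control mean over all genes (median absolute deviation 0.14, against 0.20 and 0.21). The arrays were not centred for this. Their median log2 values were 7.626, 7.638 and 7.537 in knockout replicates 1, 2 and 3 and 7.515 to 7.530 in the controls. The comparison thus partly reads scaling and does not decide whether the array of replicate 3 was poor. Undeleted cells that were mostly lymphoid may remain, and so may a difference between mice in how far the loss of Ott1 had acted; neither was tested.

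With 3 mice against 3 there are 10 splits, too few for a share under 0.05. The real split gave 103 genes and the highest of the other splits 1, so 1 of the 10 gave as many. For the lists the real split gave 9 and the highest other 9, and 5 of the 10 gave as many at the preset correlation. The other splits keep part of any genotype shift, so they do not show what chance alone gives.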

How the results depend on the processing

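No alternative was added after the values had been seen. The count of 103 genes was 76 to 108 under both other scalings, array weights, trend and robust options, without dim genes, with averaged probe sets, without x and s probe sets and over every probe set. It was 302 at adjusted p under 0.1, 2 with a plain t-test (0 shared with the 103) and 0 to 18 with 1 array left out, where fewer arrays leave less power. Rbm15 kept its direction in all 14 alternatives that refitted limma by gene and its call in 7 of these. Its change was −4.62 to −3.37, with an adjusted p of 0.0522 to 0.142, when 1 array was left out. Outside these 14 it also lost its call over every probe set (limma adjusted p = 0.0603) and with the plain t-test (adjusted p = 0.261). Nothing in the sources used here says that the replicate numbers shared by the groups mark pairs. The deviations of same-numbered arrays from their group means correlated at −0.33, −0.14 and 0.10. By these deviations 1 of 6 arrays correlated best with its own number in the other group. So few arrays cannot exclude pairing. With the replicate block 0 genes passed (1567 at unadjusted p under 0.05 in limma), the Rbm15 change was −4.09 (adjusted p = 0.0990), and 9 lists passed.

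The number of lists, 9, was 6 to 11 in 16 of 17 alternatives and 0 with an estimated correlation. The ageing list kept its call in 16 of 17 and lost it with the estimated correlation (mean 0.85, adjusted p = 0.382). The list of long-term stem cells passed in 5 of 17, with means of 0.20 after quantile normalization, 0.14 with centred arrays and 0.26 without x and s probe sets, and its mean lay between 0.15 and 0.28 with 1 array left out. The G2/M list's mean ran from −0.093 to 0.023 with 1 array left out. Of the 74 other named genes, 34 of them past the threshold, the calls that stayed numbered 0 with the replicate block, 0, 7 and 0 without knockout replicates 1, 2 and 3, and 8, 1 and 2 without control replicates 1, 2 and 3. They numbered 29 after quantile normalization, 27 with centred arrays, 26 with array weights, 28 with averaged probe sets, 29 without dim genes (all that were tested), 32 without x and s probe sets and 34 with trend and robust options. Only Kit changed direction, to 0.10 with averaged probe sets. The causes were not tested. Sex as a covariate was not run, since no array stood apart in Eif2s3y and Kdm5d (spans of 0.57 and 0.45). Signal over background could not be judged without detection calls, so changes of dim genes such as Ccr7, Spib and Cnr2 may be understated.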

Other observations

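The test of genes near Ott1 was chosen before its result was seen; genes named here follow the same rule as elsewhere. Several programmes held few or no genes past the threshold. Of 35 p53 target genes 0 passed, with 1 higher and 1 lower adjusted over the list alone. These were led by Ak1, an adenylate kinase (0.97 ± 0.16, adjusted p = 0.0594, 0.0462 without dim genes, and 0.45 with averaged probe sets), and Trp53inp1, a p53-induced nuclear protein (−0.56 ± 0.12, adjusted p = 0.107). Of 39 DNA repair genes 0 passed, also adjusted over the list alone, with the nuclease gene Exo1 at 0.77 ± 0.22 (adjusted p = 0.190) and Rad52, a recombination factor, at 0.51 ± 0.16 (adjusted p = 0.217). Among 37 antioxidant genes 0 passed by either adjustment, with sulfiredoxin (Srxn1) at 0.66 ± 0.16 (adjusted p = 0.140) and catalase (Cat) at −0.67 ± 0.23 (adjusted p = 0.257). Among 80 oxidative phosphorylation genes 0 passed by either adjustment, with cytochrome c (Cycs) at −0.47 ± 0.16 (adjusted p = 0.240) and Cox6a2 at −0.84 ± 0.30 (adjusted p = 0.263). Camera adjusted p-values of these lists were 0.572, 0.972, 0.382 and 0.991. The p53, repair and oxidative phosphorylation means (0.0035, 0.030 and 0.011) changed sign with centred arrays, and for p53 and repair the test pointed lower while the median and mean lay above 0.

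Of 56 splicing and export genes 1 fell, Rbmx, a nuclear RNA-binding protein (−0.86 ± 0.10, adjusted p = 0.0348), also adjusted over the list alone, while the list had a mean of −0.041 (camera adjusted p = 0.104). With averaged probe sets Rbmx no longer passed (−0.57, adjusted p = 0.0675). Of 44 immediate early genes 1 rose by either adjustment, Gem (1.93), and the list's mean of 0.22 held shifts of 0.36, 0.52 and −0.21 in knockout replicates 1, 2 and 3 (camera adjusted p = 0.506). Among 30 erythroid genes 0 passed over all genes and 2 were higher and 1 lower adjusted over the list alone. The carbonic anhydrase gene Car1 stood at −1.47 ± 0.28 (adjusted p = 0.0796) and Gfi1b, a repressor of erythroid and megakaryocyte cells, at 0.68 ± 0.16 (adjusted p = 0.124). By either adjustment no member passed among 64 MYC and ribosome biogenesis genes (mean 0.079, led by Mycn at 0.86 ± 0.23 and Ddx18 at 0.44 ± 0.14), 49 ribosomal protein genes (mean −0.050, led by Rpl39l at −1.14 ± 0.36 and Rpl22l1 at −0.23 ± 0.094) or 38 apoptosis regulators (mean 0.048, led by Bcl2l1 at 0.53 ± 0.14 and Bok at −0.37 ± 0.10). The same held for 43 NF-kB genes (mean 0.020, led by Traf1 at 0.84 ± 0.19 and Il6 at 0.63 ± 0.14), 34 Notch genes (mean 0.054, led by Notch3 at 0.50 ± 0.14 and Adam17 at 0.33 ± 0.10) and 36 TGF-beta genes (mean 0.10, led by Id2 at −0.42 ± 0.11 and Ski at 0.53 ± 0.15). With averaged probe sets Id2 stood at −0.14 (adjusted p = 0.637) and Ddx18 at 0.26. The camera adjusted p-values of these 6 lists were 0.466, 0.147, 0.972, 0.942, 0.770 and 0.442 in that order, and the apoptosis, NF-kB and Notch means changed sign with centred arrays. Of 9 sort and lineage genes 0 passed by either adjustment, with Il7r at −2.09 ± 0.80 (adjusted p = 0.291) and Ptprc, the gene of CD45, at −0.44 ± 0.17 (adjusted p = 0.293). Without knockout replicate 3 the Il7r change was −1.24, and without knockout replicate 2 the Ptprc change was −0.26. The mean of that list was −0.25 and its median 0.031 (camera adjusted p = 0.579). The 13 genes of the list with Rbm15, its partners and other genes of N6-methyladenosine and mRNA export had a median of 0.086 and a mean of −0.24, the latter with Rbm15 included (camera adjusted p = 0.972). The 4 sex-linked genes were too few to test, with Eif2s3y at −0.21 ± 0.15 and Xist at −0.61 ± 0.26 (adjusted p = 0.563 and 0.334). Xist was dim on all 6 arrays, at 4.41 to 5.68, so its change may be background. Leaving out 1 array moved Eif2s3y to between −0.35 and −0.11 and Xist to between −0.88 and −0.40, and Xist stood at −0.18 with averaged probe sets and −0.12 without x and s probe sets. For Srxn1, Ak1, Mycn, Id2 and Xist a dimmer probe set pointed the other way.

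The engineered Ott1 alleles may carry linked DNA of another strain, which could change neighbouring genes without any role of Ott1. Among the 100 measured genes nearest to Rbm15 on chromosome 3, in the gene order of assembly GRCm38.p6, 0 passed adjusted p 0.05 in limma, where 0.83 would be expected (one-sided Fisher exact p = 1). At unadjusted p under 0.05 the share was 18.0%, against 14.9% of other genes (Fisher exact p = 0.231). With fewer than 1 call expected, the test leaves this open. Nearest to the threshold were Rhoc (1.675, limma adjusted p = 0.0594), Ap4b1 (−1.02, 0.0606) and Gstm2 (1.73, 0.0787), chosen after their values were seen. Gstm2 stands in the ageing list, and the neighbour Chil3 in the neutrophil list. Other neighbours stand in further lists, among them the granulocyte and monocyte, mast cell, macrophage, antioxidant and TGF-beta lists. Linked DNA could thus touch any of these lists.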
